A study of Mus musculus with 12 samples.

How the data were processed

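RNA was measured by sequencing in 12 cultures of mouse osteoclasts, the multinucleated cells that resorb bone. Per the labels, bone marrow was taken from male mice of 7 to 8 weeks, macrophages were grown with the cytokine M-CSF at 30 ng/ml, and RANKL, the cytokine that drives osteoclast formation, was added from day 3 for 4 days. The libraries form 4 groups of 3, from 2 factors. The first factor is wild type against a Notch2 mutant, and the labels do not name the mutation. The second is a Hes1 gene flanked by loxP sites (Hes1 loxP, gene intact) against a deleted Hes1 (Hes1 deletion), and how the deletion was made is not given in the sources used here. Groups were taken from the labels, which call the 3 samples of a group biological replicates.

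Per the labels' protocols, stranded mRNA libraries were sequenced as paired-end reads of 75 bp in 1 pool. The deposited values are whole-number counts per gene, not normalized. Per the submitters' processing notes, HISAT2, SAMtools, Picard, HTSeq and DESeq2 were used with the mouse build GRCm38. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of a gene and of an antisense gene over its exons may not be separated. Each deposited table holds 55414 gene IDs and 5 summary rows. The summary rows were kept out of library sizes and tests. They held 15.8 to 19.0% of each file's total, of which 6.11 to 8.31 percentage points were ambiguous between genes and 6.00 to 6.45 were not uniquely aligned. Gene names were matched by ID to GENCODE M21 (GRCm38), which named 52081 IDs and left 3333 without a name. The unnamed IDs held at most 0.180% of a library's counts. Positions are from the same annotation, 1-based. Single-cell measurements named in the design text are not analysed here.

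The counts assigned to genes ranged from 13832368 to 19293772 per library. Replicates within a group differed by more than sampling noise, with a chi-square per gene of 2.32 to 7.78, so none was treated as a duplicate. The highest values, 7.43 and 7.78, both involved replicate 3 of the wild type Hes1 deletion group. Counting intervals (95%, exact binomial on the split of counts between groups) and floors (3 counts over a group) cover counting error only. They use counts summed over libraries, so the spread between cultures is left out. Reads without molecular identifiers are not independent molecules, so counting error itself may be understated.

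Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test. All 12 libraries entered 1 fit with a mean per group, TMM scaling and the filterByExpr filter (minimum count 10, minimum total 15), which kept 13403 genes. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Log2 fold changes are given with a standard error derived from the F statistic. CPM is the usual depth-scaled count, taken over the counts assigned to genes and without TMM scaling. The 5 comparisons were the Notch2 mutation with Hes1 loxP and with the Hes1 deletion, the Hes1 deletion in wild type and in Notch2 mutant cells, and the interaction. Gene lists, 25 in number, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, adjusted over the 25 lists within a comparison. A list's members were counted over all genes tested and also adjusted over the list alone. Hes1 itself fell below the filter and was compared by counts and an exact permutation test.

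Groups, comparisons, lists, the test and the alternatives listed below, except those added later, were fixed before the data were examined. So was the rule for named genes. It takes Notch2 and Hes1, and per comparison up to 10 genes higher and 10 lower with the largest log2 fold change among those past the threshold. These need a mean log2 CPM of at least 1, groups that do not overlap (which chance gives for 10% of genes) and no clone-type name. Up to 4 members of a list with the smallest adjusted p may be named as examples. Celf3, Hist1h2al and Gzmb, which belong to counts of 5 called genes, and Has2 fall outside the rule and were named after their values were seen.

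The alternatives were RLE scaling, no filter, a mean count of at least 50, DESeq2 1.42.0, limma-voom, a replicate block, each library left out, only the groups compared, and a log2 fold change of at least 1. DESeq2 was run without the edgeR filter, on 25080 genes. A fit with a stromal score as a covariate, list medians and camera tests with each library left out over the 13403 genes, and count ratios with each library left out, were added after the data were seen. The fit was tested on simulated counts for the Notch2 comparison with Hes1 loxP, with 200 changed genes among 13380. It recovered 89.0% of genes changed 1.5-fold and 99.0% of those changed 2-fold, with 12 false calls among 200. The changed genes all had a mean count of at least 50 and genes were simulated independently. Recovery at lower counts or among correlated genes was not covered.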

Results

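The transcriptomes of osteoclasts grown from bone marrow macrophages were compared between wild type and Notch2 mutant mice, each with Hes1 intact (Hes1 loxP) or with Hes1 deleted. Notch2 is a cell surface receptor and Hes1 a transcriptional repressor that Notch signals induce. Each of the 4 groups held 3 libraries. Counts assigned to genes were 13873032, 19293772 and 17979599 in wild type Hes1 loxP libraries and 13832368, 17911848 and 17781889 in Notch2 mutant Hes1 loxP libraries. They were 17283236, 18182925 and 15956749 in wild type Hes1 deletion libraries and 14573372, 16620360 and 16046113 in Notch2 mutant Hes1 deletion libraries. The values below come from these deposited counts and an edgeR quasi-likelihood fit of 13403 genes.

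Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796, GRCm38) was scarce in these cells and, over both genotypes together, scarcer after deletion. Its counts summed to 23 in wild type and 7 in Notch2 mutant Hes1 loxP libraries, and to 2 in each Hes1 deletion group. Over both genotypes, the deletion libraries held 0.0413 ± 0.0509 CPM (SD, n = 6) and the loxP libraries 0.296 ± 0.184 CPM (SD, n = 6). The ratio was 0.136, with a counting interval of 0.0348 to 0.386 (0.0811 without wild type Hes1 deletion replicate 3), and a two-sided exact permutation test over 924 splits gave p = 0.00649. Taken apart, the ratio was 0.0865 in wild type, with a counting interval of 0.00988 to 0.350 and both deletion counts in replicate 3 (0.130 and 0.134 without deletion replicates 1 and 2), and 0.30 in the Notch2 mutant, with an interval of 0.0304 to 1.57 that includes 1. The two-sided exact permutation test of each genotype gave p = 0.10, the smallest those 6 libraries allow. Between the Hes1 loxP groups, the Notch2 mutant held 0.314 times the wild type level, with a counting interval of 0.114 to 0.757. The two-sided exact permutation test of those 6 libraries gave p = 0.10, the smallest the design allows.

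Notch2 (ENSMUSG00000027878, chromosome 3, 98013527 to 98150361, GRCm38) was at 166 ± 6.67 CPM (SD, n = 3) in wild type and 156 ± 11.2 CPM (SD, n = 3) in Notch2 mutant Hes1 loxP libraries. Its log2 fold change between them was -0.07 ± 0.06 (SE), with an adjusted p of 0.659 in the edgeR quasi-likelihood test. In the Hes1 deletion libraries the Notch2 mutant differed from wild type by 0.07 ± 0.06 (SE), adjusted p = 0.865 by edgeR. The labels do not say where the mutation lies, so the summed count of the gene does not check which libraries carry it. Its exons overlap the annotated gene Gm42820.

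**Figure D1:**
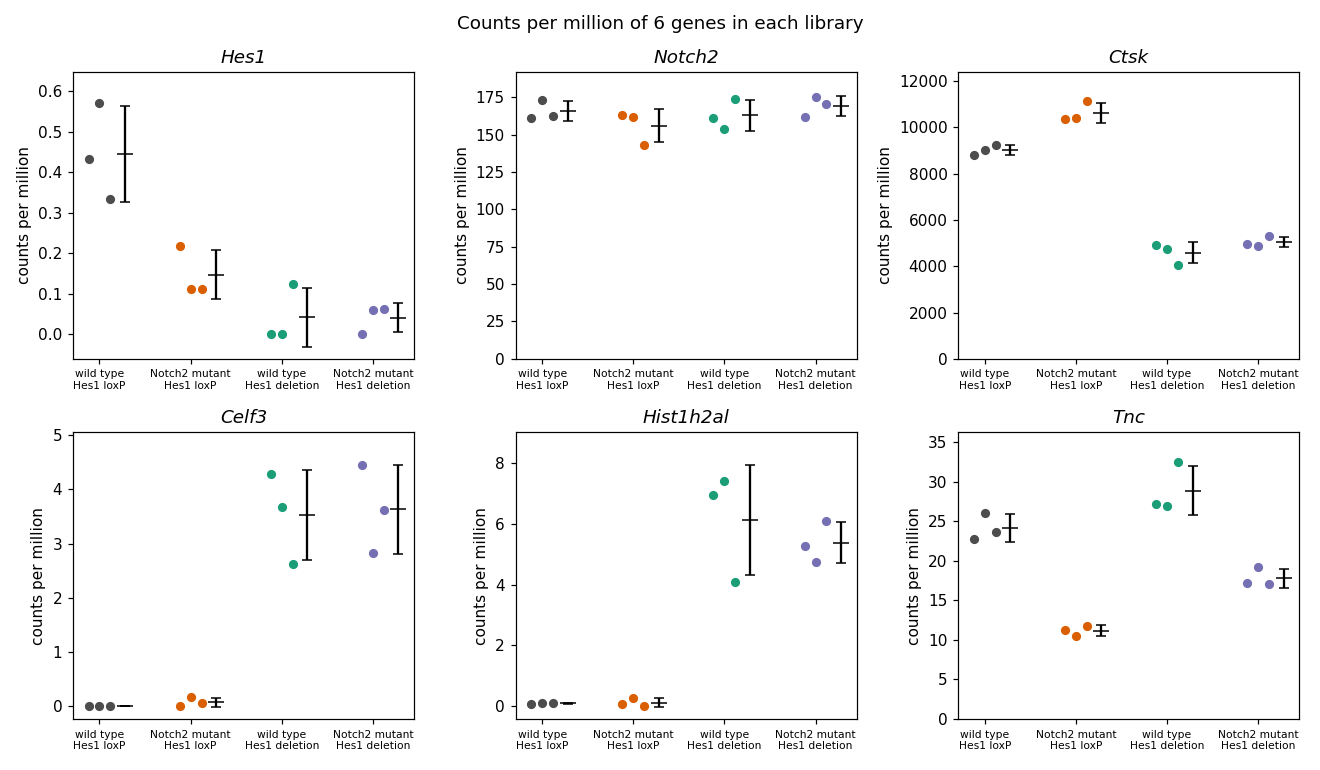
CPM (y axis, linear) of 6 genes in each of the 12 libraries (points), with the mean and SD of the 3 libraries of each group (bars) on the x axis. Ctsk lies between 4071 and 5294 CPM in the 6 Hes1 deletion libraries, below all 6 Hes1 loxP libraries, and Celf3 and Hist1h2al are near 0 in the loxP libraries.

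With Hes1 intact, Notch2 mutant osteoclasts had lower levels of Ccl12, Ccl7, Csf1, Tnc and other genes than wild type, and higher levels of a smaller set. The edgeR quasi-likelihood test called 104 genes at an adjusted p under 0.05, 19 higher and 85 lower. The lower genes included Ccl12 at -1.72 ± 0.27 (log2 fold change ± SE, n = 3 per group) and Ccl7 at -1.27 ± 0.25, both chemokines that attract monocytes. Csf1, which encodes the macrophage growth factor M-CSF, was also lower, at -1.20 ± 0.24. Tnc, the matrix glycoprotein tenascin-C, fell from 24.1 ± 1.74 CPM to 11.2 ± 0.691 CPM (SD, n = 3), a log2 fold change of -1.09 ± 0.10 with an edgeR adjusted p of 2.09e-05. These were among the 10 lowest called genes with a mean log2 CPM of at least 1, groups that did not overlap and no clone-type name. The others were Tnn (-1.34), Thbs2 (-1.15), Col12a1 (-1.05), the metalloproteinase inhibitor Timp3 (-1.29) and the surface proteins Ly6a (-1.29) and Pdpn (-1.03). The highest was Il1b, the cytokine interleukin 1 beta, at 1.04 ± 0.22. The other 9 of the 10 highest taken in the same way lay between 0.29 and 0.62: Pdk2, a kinase that restrains pyruvate dehydrogenase, Lpin1, Lpar2, Mfap3l, Oit3, Rin3, Ak1, Rxrb and Tgm2. The adjusted p of these 20 genes ranged from 2.09e-05 to 0.0410 in edgeR. With the stromal score, the mean log2 CPM of the stromal list, as a covariate chosen after the data were seen, Csf1 was at -0.56, Col12a1 at -0.37, Ly6a at -0.66 and Tnn at -0.82, none called. Of the 104 genes, only Tnc stayed called in that fit. All 104 kept their sign and their mean effect went from 0.627 to 0.530, while the median SE rose from 0.0874 to 0.126. Tnc, Timp3, Il1b and Tgm2 overlap antisense genes, whose reads may be included. Has2, a hyaluronan synthase gene named after its values were seen, had 41 counts in wild type and 2 in the mutant, a ratio of 0.0504 with a counting interval of 0.00590 to 0.194 (0.0789 without Notch2 mutant Hes1 loxP replicate 2).

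Of the osteoclast effector and fusion genes, 19 of 25 had positive values, with a median log2 fold change of 0.16. Only Ocstamp, needed for osteoclast fusion, passed over all genes (0.25 ± 0.06, edgeR adjusted p = 0.0493), while 15 were higher and 2 lower adjusted over the list alone. Ocstamp did not pass under 11 of its 19 alternatives. Acp5, which encodes the osteoclast enzyme TRAP, was at 0.34 ± 0.08 (edgeR adjusted p = 0.0509). The list was higher by camera (adjusted p = 1.11e-07), with adjusted p = 0.127 with an estimated correlation and 0.0277 by fry. Of the 16 vacuolar ATPase subunits, which acidify the resorption space, Atp6v1f rose (0.23 ± 0.05) and 15 had positive values. Adjusted over the list alone 8 were higher and 1 lower, and the list was higher by camera (adjusted p = 2.88e-06, and adjusted p = 0.149 with an estimated correlation). Atp6v1f had an edgeR adjusted p of 0.0464 and did not pass under 11 of its 19 alternatives.

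Metabolic lists were higher by small amounts. The 53 nuclear-encoded oxidative phosphorylation genes had a median of 0.09, with 51 positive, 1 called (Uqcrfs1, 0.17 ± 0.04) and 2 called adjusted over the list alone (camera adjusted p = 1.02e-12, and adjusted p = 0.149 with an estimated correlation). Uqcrfs1 had an edgeR adjusted p of 0.0464 and did not pass under 13 of its 19 alternatives. All 17 tested genes of the tricarboxylic acid cycle had positive values, median 0.09, none called over all genes and 5 adjusted over the list alone (camera adjusted p = 2.27e-07, and adjusted p = 0.127 with an estimated correlation). Cholesterol synthesis and uptake genes had a median of 0.22, 9 of 21 higher adjusted over the list alone (camera adjusted p = 3.98e-08, and adjusted p = 0.149 with an estimated correlation). Glycolysis genes had a median of 0.12 (camera adjusted p = 0.00206, and adjusted p = 0.442 with an estimated correlation), Aldoc standing at 0.54 ± 0.13. Fatty acid oxidation genes had a median of 0.10 (camera adjusted p = 0.00619, and adjusted p = 0.149 with an estimated correlation), although Cd36, a fatty acid receptor also found on macrophages, fell, at -0.73 ± 0.11. Without wild type Hes1 loxP replicate 3 neither the glycolysis nor the fatty acid oxidation list passed (camera adjusted p = 0.0542 for each), and the glycolysis median was 0.19 without Notch2 mutant Hes1 loxP replicate 2.

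Macrophage and monocyte genes were lower, with 18 of 22 negative and a median of -0.26, or -0.16 without wild type Hes1 loxP replicate 1. Msr1 (-0.47 ± 0.08), Fcgr1 (-0.83 ± 0.14) and Adgre1 (-0.42 ± 0.08), all macrophage surface proteins, were called, and 11 adjusted over the list alone (camera adjusted p = 1.92e-10, and adjusted p = 0.127 with an estimated correlation). Fcgr1 lies on chromosome 3 (96282909 to 96293969), within 5 Mb of Notch2. Interferon response genes had a median of -0.37, or -0.19 without the same replicate, with Oasl1 called (-0.37 ± 0.08) and 15 lower adjusted over the list alone (camera adjusted p = 5.20e-13, and adjusted p = 0.203 with an estimated correlation). Among inflammatory cytokines and chemokines, Ccl6, Ccl7 and Ccl12 fell and Il1b rose (median -0.22, or -0.40 without Notch2 mutant Hes1 loxP replicate 1, camera adjusted p = 2.12e-05, and adjusted p = 0.118 with an estimated correlation). All 26 cell cycle genes had negative values, median -0.13, none called (camera adjusted p = 5.92e-08, and adjusted p = 0.297 with an estimated correlation). Neutrophil genes had a median of -0.28, with Mmp8 called (-0.46 ± 0.10; camera adjusted p = 0.00219, and adjusted p = 0.428 with an estimated correlation). The neutrophil list did not pass without replicate 3 of wild type Hes1 loxP (median -0.20, camera adjusted p = 0.188) or of Notch2 mutant Hes1 loxP (-0.18, 0.110). With the stromal score as a covariate Oasl1 was at -0.25 and Mmp8 at -0.30, neither called (edgeR adjusted p = 0.383 for each). MHC class II and dendritic cell genes had a median of 0.39 and none called (camera adjusted p = 0.00206, and adjusted p = 0.378 with an estimated correlation). They did not pass without wild type Hes1 loxP replicate 2 (median 0.22, camera adjusted p = 0.142) or Notch2 mutant Hes1 loxP replicate 1 (0.26, 0.0733). Genes of stromal cells and osteoblasts, a cell type other than osteoclasts, moved with these groups, at 322 ± 24.3 CPM summed over the list in wild type and 219 ± 75.6 CPM in the mutant (SD, n = 3). Their median was -0.64, or -0.33 without Notch2 mutant Hes1 loxP replicate 2, and 14 of 15 were negative (camera adjusted p = 3.33e-09, and adjusted p = 0.127 with an estimated correlation). Cxcl12 was called, with 36 counts in wild type and 4 in the mutant. The ratio was 0.115 with a counting interval of 0.0297 to 0.320, or 0.0398 and 0.180 without Notch2 mutant Hes1 loxP replicates 1 and 2. Cxcl12 did not pass under 11 of its 17 alternatives.

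The remaining 11 lists did not pass by camera in this comparison. They hold Notch targets, Notch receptors and processing, RANK signalling factors, repressors of osteoclast formation, podosome, mitochondrially encoded, amino acid stress, endoplasmic reticulum stress, lymphocyte, mast cell to megakaryocyte, and endothelial genes. Among them Id1, a Notch target, was at -0.55 ± 0.15 (edgeR adjusted p = 0.0956) and Rbpj, which mediates Notch transcription, at -0.18 ± 0.05 (edgeR adjusted p = 0.0625). Pf4, a platelet chemokine also made by macrophages, was called at -0.69 ± 0.08. By fry, 8 of the 25 lists passed. The count of 104 genes fell to 26 without wild type Hes1 loxP replicate 1, 35 without replicate 2, 46 without Notch2 mutant Hes1 loxP replicate 2 and 28 without replicate 3. It rose to 289 without wild type Hes1 deletion replicate 3, a library of neither group that enters the shared spread. It was 244 by DESeq2, which also left out the edgeR filter (25080 genes), and 657 with no filter. It was 15 at a log2 fold change of at least 1, and 2 with the stromal score as a covariate.

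**Figure D2:**
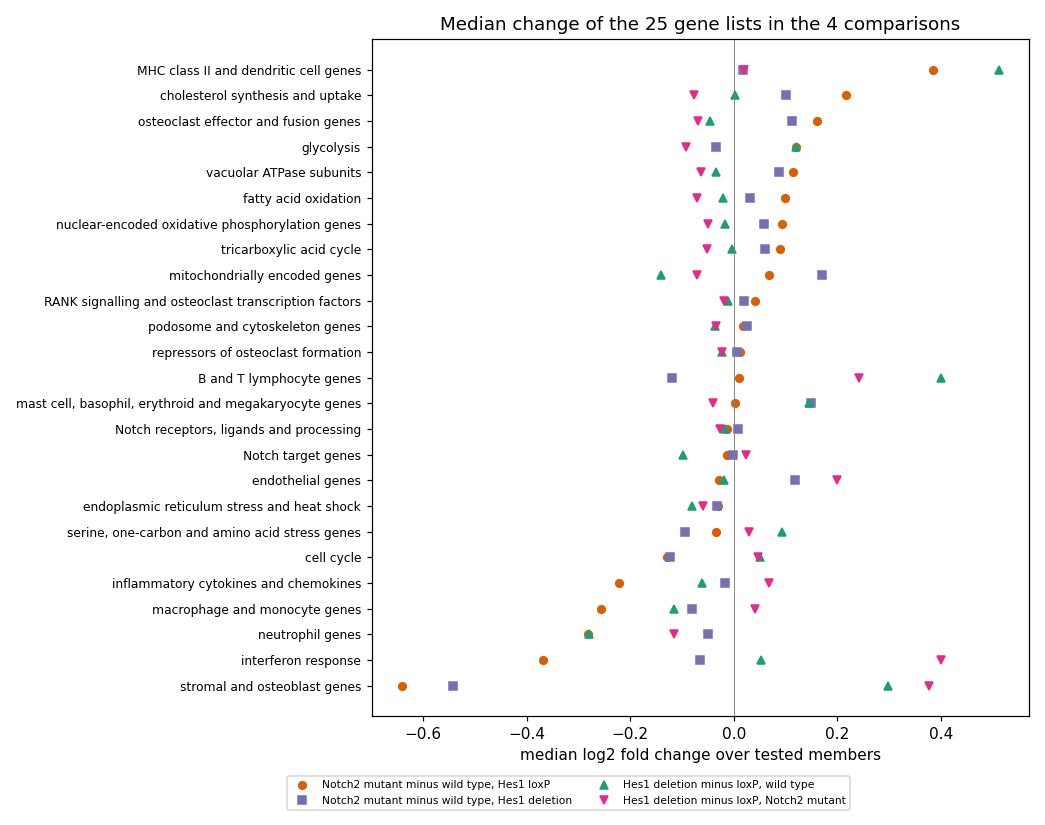
Median log2 fold change (x axis) over the tested members of each of 25 gene lists (y axis) in the 4 comparisons (symbols). Stromal and osteoblast genes have medians of -0.64 and -0.54 in the Notch2 comparisons and 0.30 and 0.38 in the Hes1 comparisons.

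Few genes differed between the Hes1 deletion and Hes1 loxP libraries of wild type cells. The edgeR quasi-likelihood test called 5, of which 3 were higher and 2 lower. Ctsk (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362), the main collagen-degrading protease of osteoclasts, fell from 9026 ± 209 CPM to 4586 ± 456 CPM (SD, n = 3), a log2 fold change of -0.99 ± 0.07 with an edgeR adjusted p of 4.84e-07. Pf4 fell, at -0.57 ± 0.08 (edgeR adjusted p = 0.00609), and Cav1, the caveolae protein caveolin 1, rose, at 0.32 ± 0.06 (edgeR adjusted p = 0.0438). Celf3 (chromosome 3, 94478295 to 94492198), an RNA-binding protein gene, had 0 counts in the Hes1 loxP libraries and 183 in the deletion libraries, at least 60.7-fold higher against a floor of 3 counts over the group (37.8 and 39.3 without wild type Hes1 loxP replicates 2 and 3, where fewer reads stand behind the floor). Hist1h2al (chromosome 13, 51202727 to 51203065), a histone H2A copy annotated as a processed pseudogene, had 5 and 320 counts, a ratio of 63.7 with a counting interval of 27.0 to 197. Its annotated transcript of 339 bases is 99.4% identical to H2A copies on chromosome 3, so the assignment of its reads is uncertain. Celf3 and Hist1h2al also overlap antisense genes, Riiad1 and Gm44341.

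No list member other than Ctsk and Pf4 was called. The other 24 tested osteoclast effector genes had a median of -0.06 averaged over both Hes1 deletion comparisons, although the list with Ctsk was lower by camera (adjusted p = 3.55e-07, and adjusted p = 0.267 with an estimated correlation). Stromal genes were positive in 15 of 15 members, median 0.30, with Postn at 0.69 ± 0.25 (camera adjusted p = 1.79e-05, and adjusted p = 0.321 with an estimated correlation). MHC class II and dendritic cell genes had a median of 0.51, with H2-Ab1 at 0.51 ± 0.16 and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.14e-05, and adjusted p = 0.321 with an estimated correlation). Neutrophil genes had a median of -0.28, with Camp at -0.78 ± 0.20 and Ngp at -0.58 ± 0.15, and 7 were lower adjusted over the list alone (camera adjusted p = 3.47e-06, and adjusted p = 0.321 with an estimated correlation). Macrophage genes had a median of -0.12 (camera adjusted p = 0.000224, and adjusted p = 0.421 with an estimated correlation). Without wild type Hes1 loxP replicate 1 the macrophage list did not pass (median -0.04, camera adjusted p = 0.364), and its median was -0.07 without wild type Hes1 deletion replicate 1. The neutrophil median was -0.18 without wild type Hes1 loxP replicate 3, and the MHC class II median 0.32 without wild type Hes1 deletion replicate 2. In all 14 lists passed by camera, and fry passed 0 of 25, with a smallest fry adjusted p of 0.266. Pf4 did not pass without wild type Hes1 loxP replicates 2 or 3 or wild type Hes1 deletion replicate 1 (edgeR adjusted p = 0.0598, 0.0678 and 0.0840). Cav1 did not pass under 13 of its 19 alternatives, among them each wild type library left out except Hes1 deletion replicate 3, and the stromal score as a covariate (edgeR adjusted p = 0.411). The count of 5 genes was 3 without wild type Hes1 loxP replicate 2, 3 without replicate 3, 3 without wild type Hes1 deletion replicate 1 and 26 without wild type Hes1 deletion replicate 3. It was 135 with no filter and 2 with a mean count of at least 50, which leaves out Celf3 and Hist1h2al and where Cav1 did not pass (edgeR adjusted p = 0.0817, 1.40e-05 to 0.411 over its 19 alternatives).

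In Notch2 mutant cells the Hes1 deletion and Hes1 loxP libraries differed in the same 3 leading genes. The edgeR quasi-likelihood test called 5 genes, 4 higher and 1 lower. Ctsk fell from 10631 ± 434 CPM to 5048 ± 219 CPM (SD, n = 3), a log2 fold change of -1.10 ± 0.07 with an edgeR adjusted p of 8.89e-08. Celf3 had 4 counts before and 170 after deletion, a ratio of 44.6 with a counting interval of 17.1 to 165. Without Notch2 mutant Hes1 loxP replicate 2, which held 3 of the 4, it was 114, with an interval of 20.1 to 4520. Hist1h2al had 6 and 254, a ratio of 44.4 with a counting interval of 20.1 to 122. Without the same library, which held 5 of the 6, it was 170, with an interval of 30.2 to 6740, and without Notch2 mutant Hes1 loxP replicate 3 it was 28.4. Tnc rose, at 0.64 ± 0.10 (edgeR adjusted p = 0.0169), from 11.2 ± 0.691 to 17.8 ± 1.22 CPM (SD, n = 3). Gzmb, a cytotoxic protease, had 4 and 72 counts, a ratio of 18.9 with a counting interval of 7.06 to 71.1 (edgeR adjusted p = 0.0314). Without Notch2 mutant Hes1 loxP replicate 1, which held 3 of the 4, the ratio was 54.4, with an interval of 9.46 to 2178, and without replicate 2 it was 12.05. In wild type cells Gzmb had 27 counts with Hes1 loxP and 45 with the deletion, and it was not called there. With the stromal score as a covariate neither Tnc (edgeR adjusted p = 0.395) nor Gzmb (0.515) passed, by limma-voom both had an adjusted p of 0.0588, and with the replicate block Gzmb had an edgeR adjusted p of 0.0639. Tnc did not pass without Notch2 mutant Hes1 loxP replicates 1 or 2 or Hes1 deletion replicate 2 (edgeR adjusted p = 0.0609, 0.190 and 0.146), nor Gzmb without Notch2 mutant Hes1 loxP replicates 2 or 3 or Hes1 deletion replicates 1 or 3 (0.279, 0.264, 0.133 and 0.0945).

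All 26 interferon response genes had positive values, with a median of 0.40, none called over all genes and 15 adjusted over the list alone. Ifih1, a sensor of viral RNA, was at 0.40 ± 0.09 and Rtp4 at 0.55 ± 0.14 (camera adjusted p = 1.41e-26, and adjusted p = 0.261 with an estimated correlation). Stromal genes had a median of 0.38, with Postn at 0.82 ± 0.28 (camera adjusted p = 4.67e-06, and adjusted p = 0.299 with an estimated correlation). That list did not pass without Notch2 mutant Hes1 loxP replicate 2 (median 0.07, camera adjusted p = 0.250), and its median was 0.58 without replicate 3 and 0.19 without Notch2 mutant Hes1 deletion replicate 1. Oxidative phosphorylation genes had a median of -0.05 (camera adjusted p = 1.11e-05, and adjusted p = 0.429 with an estimated correlation), and glycolysis genes one of -0.09, or -0.17 and -0.05 without Notch2 mutant Hes1 loxP replicates 2 and 3 (camera adjusted p = 0.00241, and adjusted p = 0.507 with an estimated correlation). The osteoclast list, Ctsk included, was lower by camera (adjusted p = 7.97e-09, and adjusted p = 0.261 with an estimated correlation). In all 15 lists passed by camera and fry passed 0 of 25, with a smallest fry adjusted p of 0.139. The count of 5 genes was 3 without Notch2 mutant Hes1 loxP replicate 2, 3 by limma-voom, 110 with no filter and 2 with a mean count of at least 50.

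All 5 genes called for the Hes1 deletion in wild type cells had the same sign in Notch2 mutant cells, and 3 (Ctsk, Celf3 and Hist1h2al) were called in both, against 0.00187 for independent lists. Of the 5, 4 did so at an unadjusted edgeR p under 0.05. Pf4 barely differed in Notch2 mutant cells, at 31.5 ± 2.74 CPM with Hes1 loxP and 31.5 ± 3.57 CPM with the deletion (SD, n = 3). Other splits of the 6 Notch2 mutant libraries also put all 5 on 1 side. Each such split mixes the groups unevenly and keeps part of the difference between them, so it does not measure chance agreement. An alteration carried with the deletion in both genotypes could also give such shared calls. The agreement of both genotypes therefore does not assign these changes to Hes1 loss. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.242 and a Spearman correlation of 0.108.

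In cells without Hes1, the Notch2 mutation left 2 genes past the threshold of the edgeR quasi-likelihood test, both lower. Tnc was at 28.9 ± 3.12 CPM in wild type and 17.8 ± 1.22 CPM in the mutant (SD, n = 3), a log2 fold change of -0.68 ± 0.09 with an edgeR adjusted p of 0.00812. Timp3 fell, at -1.32 ± 0.21 (edgeR adjusted p = 0.0452). The osteoclast effector list was higher, with 22 of 25 positive and a median of 0.11, Tcirg1 standing at 0.21 ± 0.06 and Acp5 at 0.23 ± 0.08 (camera adjusted p = 1.10e-10, and adjusted p = 0.121 with an estimated correlation). Vacuolar ATPase subunits had a median of 0.09 (camera adjusted p = 7.94e-07, and adjusted p = 0.273 with an estimated correlation) and oxidative phosphorylation genes one of 0.06, or 0.03 without wild type Hes1 deletion replicate 3 (camera adjusted p = 6.55e-08, and adjusted p = 0.384 with an estimated correlation). Mitochondrially encoded genes had a median of 0.17, or 0.11 without Notch2 mutant Hes1 deletion replicate 3, with mt-Co2 at 0.28 ± 0.07 (camera adjusted p = 1.20e-05, and adjusted p = 0.273 with an estimated correlation). All 26 cell cycle genes were again negative, median -0.12 (camera adjusted p = 4.51e-13, and adjusted p = 0.273 with an estimated correlation). Stromal genes again moved with these groups, with 14 of 15 negative, a median of -0.54 and 6 lower adjusted over the list alone (camera adjusted p = 1.93e-13, and adjusted p = 0.121 with an estimated correlation). In all 11 lists passed by camera and fry passed 0 of 25, with a smallest fry adjusted p of 0.165. With the stromal score as a covariate neither Tnc (-0.56) nor Timp3 (-1.08) passed (edgeR adjusted p = 0.720 for both). The count of 2 genes was 0 without Notch2 mutant Hes1 deletion replicate 1 or replicate 3, and 1 without replicate 2. It was 1 without wild type Hes1 loxP replicate 2, Notch2 mutant Hes1 loxP replicate 1 or wild type Hes1 deletion replicates 1 or 2, 5 without wild type Hes1 deletion replicate 3, and 138 with no filter.

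Whether the effect of the Notch2 mutation depended on Hes1 was tested as the interaction. The edgeR quasi-likelihood test called 0 genes, with 506 at an unadjusted p under 0.05 where 670 would arise by chance, and DESeq2 and limma-voom called 0 each. Without wild type Hes1 deletion replicate 3 the count was 12, and with no filter 63. By camera 8 lists differed, among them interferon response (median difference 0.31, adjusted p = 7.08e-10, and adjusted p = 0.641 with an estimated correlation) and glycolysis (median difference -0.24, adjusted p = 1.87e-07, and adjusted p = 0.589 with an estimated correlation). The interferon difference was 0.15 without wild type Hes1 loxP replicate 1, and the glycolysis difference -0.14 without Notch2 mutant Hes1 loxP replicate 3 or wild type Hes1 deletion replicate 2. By fry 0 of the 25 lists differed, with a smallest adjusted p of 0.684.

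Of the 104 genes called for the Notch2 mutation with Hes1 intact, 102 had the same sign with Hes1 deleted, 56 of them at an unadjusted p under 0.05, and 2 were called in both. The 104 genes were measured in the same libraries and are not independent replicates. Another split of the 6 Hes1 deletion libraries put 101 of them on 1 side. Such a split mixes the groups unevenly and keeps part of the Notch2 difference, so it does not measure chance agreement. Their mean absolute log2 fold change was 0.63 with Hes1 intact, and their mean with the same sign was 0.28 with Hes1 deleted, a ratio of 0.448. The genes were selected on the first of these values, which raises it. Across all genes the Pearson correlation was 0.260 and the Spearman correlation 0.291, a description across genes that are not independent replicates.

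**Figure D3:**
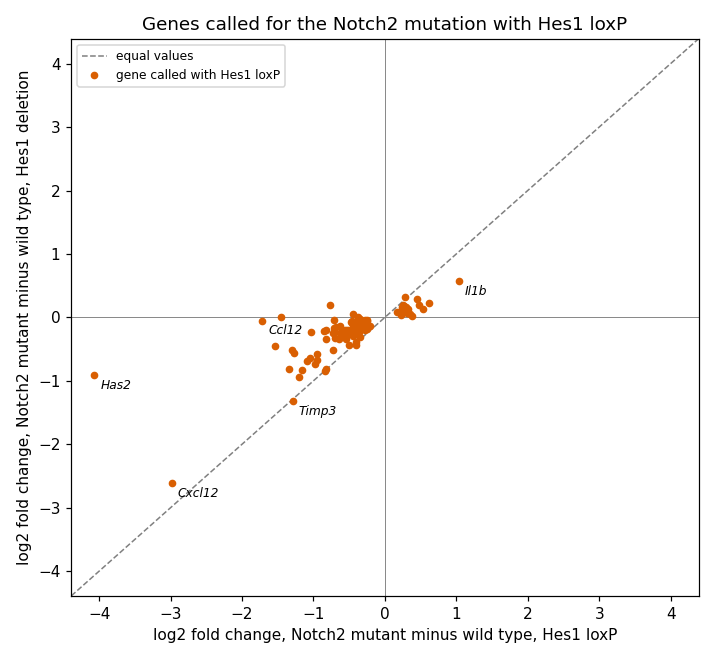
Log2 fold change of Notch2 mutant minus wild type with Hes1 loxP (x axis) and with the Hes1 deletion (y axis) for the 104 genes called with Hes1 loxP (points), with a dashed line of equal values. Most points lie between the line and 0 on the y axis, and 102 share their sign.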

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

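The tests of a lower share of osteoclasts, of the chromosome 3 segment, of stromal cells, of lists with each library left out, of a common dilution and of replicate 3 of the wild type Hes1 deletion group were chosen only after the result was seen.

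The effect of the Notch2 mutation differed with the Hes1 deletion for 8 gene lists by a camera test of the interaction. The median log2 interaction was -0.037 for oxidative phosphorylation (camera adjusted p = 0.00756), -0.039 for the tricarboxylic acid cycle (0.0233), -0.235 for glycolysis (1.87e-07) and -0.066 for cholesterol synthesis (0.0233). It was 0.159 for macrophage genes (5.02e-06), 0.308 for interferon response (7.08e-10), 0.105 for inflammatory cytokines (0.00325) and -0.247 for MHC class II and dendritic cell genes (0.00181). None of the 8 passed with an estimated correlation (adjusted p = 0.424 to 0.761) or by fry (0.684 to 0.827). With each library left out, the oxidative phosphorylation, tricarboxylic acid, cholesterol and MHC class II lists each lost their call at least once (highest camera adjusted p 0.158, 0.253, 0.389 and 0.163). The macrophage median was 0.026 and the interferon median 0.150 without wild type Hes1 loxP replicate 1, and the inflammatory median was 0.028 without Notch2 mutant Hes1 loxP replicate 2. Over all libraries left out in turn, the inflammatory median reached 0.204, the macrophage median 0.229 and the interferon median 0.46. The MHC class II median ran from -0.468 to -0.044 and the glycolysis median from -0.321 to -0.137. For oxidative phosphorylation it ran from -0.075 to -0.019, for the tricarboxylic acid cycle from -0.064 to -0.01 and for cholesterol synthesis from -0.121 to -0.047. Of 50 drawn splits, the real one included, 28 gave at least the 506 genes at an unadjusted p under 0.05, so chance cannot be excluded for that count, and the highest other split gave 1780, which may point to a structure among the samples or to genes that move together, neither of which was tested.

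Ctsk was lower, and Celf3 and Hist1h2al higher, in both Hes1 deletion comparisons. A lower share of osteoclasts as the reason for the fall of Ctsk is argued against. The other 24 osteoclast effector genes had a median of -0.0576 (SD 0.0405) over both comparisons, while Ctsk was at -1.05 ± 0.0490 (SE). A slightly lower share is not excluded. With Ctsk, 22 of 25 effector genes were negative in wild type and 20 of 25 in the mutant. Of the vacuolar ATPase subunits, 13 of 16 and 16 of 16 were negative (camera adjusted p = 0.0154 and 0.000702, and 0.479 and 0.35 with an estimated correlation). An altered chromosome 3 segment around Ctsk is a candidate explanation: 24 of 104 other tested genes within 5 Mb (23.1%) had an unadjusted p under 0.05, against 6.85% of all genes, at percentile 99.3 of equal windows (98.6 without histone and S100 genes). A Cre insertion at Ctsk, in common use to delete floxed genes in osteoclasts, would be such an alteration, but the labels do not name one, and an effect of Hes1 loss on Ctsk stays open. Hist1h2al reads could come from an H2A copy on chromosome 3, since those copies are 99.4% identical over its whole length.

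Macrophage and stromal genes were lower by camera in the Notch2 mutant Hes1 loxP cultures, although both lists had adjusted p = 0.127 with an estimated correlation, and by fry macrophage genes had 0.0499 and stromal genes 0.0548. A common dilution of all other cell types is argued against only weakly, by MHC class II genes. Their median lay 1.03 ± 0.261 above that of stromal genes (SE over list members, which are correlated, so it understates the spread). The difference of the mean list scores per library was 1.01 ± 0.278 (SE, n = 3 per group), and at least 0.821 ± 0.226 with each of the 6 libraries left out. These lists had the highest and lowest medians of those compared and were picked after the values were seen, which widens the gap. The MHC class II list itself had a camera adjusted p of 0.378 with an estimated correlation. Stromal cells as the carriers of the lost macrophage transcripts stay open, because the lower macrophage score, -0.227 ± 0.0884 (SE), became -0.154 ± 0.128 with the stromal score as a covariate over 12 libraries, too wide to decide. With the stromal score as a covariate all 104 genes kept their sign and their mean effect went from 0.627 to 0.530, while the median SE rose from 0.0874 to 0.126, 2 genes were called, 1 of them among the 104, and Csf1 went from -1.20 to -0.56. An effect of stromal cells through factors such as Csf1, and an effect of the mutation in macrophages themselves, stay open and untested.

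The Notch2 mutation gave 104 called genes with Hes1 loxP and 2 with the Hes1 deletion. Replicate 3 of the wild type Hes1 deletion group as a reason stays open. Without it the counts were 289 and 5, but the second comparison had then lost a library of its own and the first had not. With any other Hes1 deletion library left out, the second count was 0 or 1. Equal effects missed by chance stay open: in 0% of 50 simulated experiments with equal effects was the ratio as low as 0.448 (range 0.594 to 0.740), but the simulation assumed its effect sizes and independent genes. The interaction test itself called 0 genes by edgeR, DESeq2 and limma-voom, with 506 at an unadjusted p under 0.05.

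The 10 splits of each 6 libraries are too few for a share under 0.05. The real split and the highest other gave 104 and 1 genes for the Notch2 mutation with Hes1 loxP, and 5 and 13 for the Hes1 deletion in wild type. They gave 5 and 0 for the Hes1 deletion in the mutant, and 2 and 0 for the Notch2 mutation with the Hes1 deletion. Genes of 1 sign numbered 102 and 101 for the Notch2 effects, and 5 and 5 for the Hes1 effects, where 6 of the 10 splits reached 5. Each other split mixes the groups unevenly and keeps part of the real difference. These sign counts therefore do not measure chance agreement.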

How the results depend on the processing

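Only the stromal score covariate and the list tests and count ratios with each library left out were chosen after the data were seen. Of 44 calls of named genes, 7 held under each of the up to 19 alternatives run per gene (scaling, filters, tools, block, covariate and each library left out): Tnc for the Notch2 mutation with Hes1 loxP, and Ctsk, Celf3 and Hist1h2al in both Hes1 deletion comparisons. Single genes were not recomputed at a log2 fold change of at least 1, where 0 lower genes and so not Ctsk passed in wild type, nor in a fit of only the groups compared. No called gene reversed under the alternatives run per gene. Celf3 and Hist1h2al had no value at a mean count of at least 50, and Hes1 lay below the count filter of the gene-wise fit. Counts are given below in the order Notch2 mutation with Hes1 loxP, Hes1 deletion in wild type, Hes1 deletion in the mutant, Notch2 mutation with the Hes1 deletion, and interaction, against 104, 5, 5, 2 and 0. The cause was not tested unless given.

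With no filter on low counts they were 657, 135, 110, 138 and 63, with 587 genes of the same sign for the Notch2 effects (102 otherwise) and 95 for the Hes1 effects (5 otherwise). At a mean count of at least 50, the counts 5, 5 and 2 became 2, 2 and 1, and 2 Hes1 effects had the same sign. Celf3, Hist1h2al and Gzmb were then not tested, while Cav1 in wild type (edgeR adjusted p = 0.0817, range 1.40e-05 to 0.411) and Timp3 with the Hes1 deletion (0.0726, range 3.24e-15 to 0.720) were tested and did not pass. DESeq2 called 244 genes (74 higher, 170 lower) for the Notch2 mutation with Hes1 loxP, 232 of the same sign. That run also left out the edgeR filter (25080 genes), so tool and filter changed together. Limma-voom called 3 for the Hes1 deletion in the mutant and 1 for the Notch2 mutation with the Hes1 deletion. At an absolute log2 fold change of at least 1 the counts were 15, 2, 4, 1 and 0, by construction. With the stromal score as a covariate they were 2, 4, 3, 0 and 0, and 7 calls of named genes moved by over 1.5 times, all smaller (Csf1, Col12a1, Ly6a, Tnn, Oasl1, Mmp8 and Cxcl12, a member of the score). Col1a1 (Notch2 mutation, Hes1 loxP) and Col5a1 (Notch2 mutation, Hes1 deletion), neither called, reversed to 0.0799 and 0.0195. RLE scaling left all counts within 1.5 times, and so did a fit of only the groups compared for the 4 counts it gives, with 80 of the 104 genes among its 119. With an estimated correlation 0 of the 25 lists passed in each of the 5 comparisons, and by fry 8, 0, 0, 0 and 0. With each library left out, camera called 12 to 16, 9 to 15, 10 to 16, 9 to 14 and 4 to 10 lists, against 14, 14, 15, 11 and 8, and 4, 10, 8, 3 and 4 of these lost their call at least once.

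With each library left out, the ranges were 26 to 289, 3 to 26, 3 to 6, 0 to 5 and 0 to 12, with 26 to 228 genes of the same sign for the Notch2 effects and 3 to 14 for the Hes1 effects. Without replicate 3 of the wild type Hes1 deletion group the counts were 289, 26, 6, 5 and 12, each at the top of its range. The Notch2 count with Hes1 loxP was 26 and 35 without wild type Hes1 loxP replicates 1 and 2, and 46 and 28 without Notch2 mutant Hes1 loxP replicates 2 and 3.

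With the replicate number as a block the counts were 148, 5, 4, 2 and 0, with 141 and 4 genes of the same sign, and camera called the same number of lists, none lost or gained. Fry with the block passed 6, 0, 0, 0 and 0 lists, against 8, 0, 0, 0 and 0 without it. Same-numbered samples correlated at 0.077 to 0.107 in the first comparison, where 3 of 3 correlated best with their own number. A weak pairing by number is therefore not excluded there. In the next 3 comparisons they correlated at -0.077 to 0.021, -0.019 to 0.095 and -0.072 to 0.069. There 0, 1 and 1 of 3 correlated best with their own number.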

Other observations

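Both tests here were chosen before their result was seen. A segment carried along with an altered gene could leave changed genes near it. Around Notch2, 21 of 106 tested genes within 5 Mb (19.8%) had an unadjusted p under 0.05 for the Notch2 mutation, against 16.3% of all genes, at percentile 75.5 of equal windows. Around Hes1, 4 of 49 (8.16%) did so for the Hes1 deletion, against 6.86%, at percentile 72.8. Neither value decides for or against such a segment. Fcgr1, a macrophage list gene, was among the 21 near Notch2, with a log2 fold change of -0.51 averaged over both Notch2 comparisons.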
